A study of Gallus gallus with 6 samples.

How the data were processed

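The samples were 6 cultures of DT40, a chicken B cell line derived from a bursal lymphoma. Of these, 3 were wild type and 3 were IRF4 knockout, and per the labels' protocols each was an independent culture. Per the labels' protocols, total RNA was purified on a silica column with DNase treatment and amplified and labelled with Cy3 by a one-colour kit. The labels' separate dye field reads biotin; the one-colour Cy3 protocol and the single green channel of the scanner files were followed here. Groups and replicate numbers came from the sample titles.

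Per the file headers, each array was a one-colour Agilent chicken design with 45220 spots, read by the authors with Feature Extraction 10.7.1.1, and its annotation named the galGal3 build. The intensity values used were the processed green signals, which per the file headers were background-subtracted on a linear scale and not yet scaled between arrays. Flags for spots above background and for outliers came from the same deposited files as codes of 0 and 1, and the median and background intensities in them served an alternative. The authors' processed table held linear intensity values for the same arrays. Its columns correlated with the log2 scanner signals of their own arrays at r of 0.999 or above, and each had the same median of 225.7 and the same 75th percentile of 2695. They had therefore been brought to 1 common distribution, and the method for that is not given in the sources used here. The submitters' processing notes name limma and R 2.12.0 without saying what each did.

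The depth of an array is limited by its signal over background. Between 62.4% (wild type replicate 3) and 68.2% (wild type replicate 2) of the 43803 gene spots were well above background, no spot was saturated, and between 72 and 152 gene spots an array were flagged as outliers. The 75th percentile of the signal lay 98.2 to 111.1 times above the median background, and replicate spots of a probe had median coefficients of variation between 3.59% and 4.29%. The number of arrays, 3 in each group, sets the precision of each comparison between these cultures. The number of knockout clones behind them is not given in the sources used here, so errors and p-values may not cover the spread between clones.

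Signals were taken as log2 and each array's 75th percentile was subtracted. Control spots (1417 an array) and outlier-flagged spots were left out, and spots of 1 probe were averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 group. A gene was represented by its probe with the highest mean signal over the 6 arrays. Accessions of probes were matched without versions to a RefSeq table of the GRCg7b assembly: 10691 of 43603 probes (24.5%) gained the name of 1 of 4932 genes, no probe gained several, and the other 32912 kept the accession given by the array. Features are these genes plus the unnamed accessions, 31529 in all, and 19802 passed the filter. The table's assembly differs from that of the array's annotation, so no coordinates are printed, and it served only for names and for which genes share a chromosome. Older symbols in the gene lists were matched through the table's synonyms. By this route BLNK resolved to SH2D6, CD80 to CD88, RPS4X to RPS4Y1 and FOXP3 to FOXP1, so the value given for FOXP1 among the T cell markers is not one for FOXP3. Lists were also tested without members matched only through a synonym. Of the genes to be named whatever their result, INPP5D and PRDM1 had no probe with a matched accession and are not analysed here, and some others are not reported here.

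Knockout was compared with wild type by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A log2 fold change is knockout minus wild type, and its error is limma's standard error (SE). Where a probe was not well above background on any array of a group, the fold change is given as at least N-fold. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The 20 gene lists, the named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. Lists were tested with camera (preset correlation 0.01), which compares a list with all other features, Benjamini-Hochberg adjusted over the 20 lists. Beside it stood camera with an estimated correlation, and fry, which asks if the members of a list move on balance one way without comparing them with other genes. A list needed at least 5 measured genes. Camera used members with a value on all arrays, which left 18 of 19 B cell transcription factors, 7 of 8 fibroblast markers and 11 of 12 myeloid markers; counts, means and medians cover all tested members. IRF4 was also tested by an exact permutation test, two-sided.

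The named genes were chosen by a rule: IRF4; the 12 rises and 12 falls with the largest fitted log2 fold changes among called genes with a RefSeq symbol whose 3 knockout arrays lay on the same side of all 3 wild-type arrays and whose signal was well above background on all arrays of the brighter group; in each list up to 5 called members with the smallest adjusted p; and a set of B cell genes whatever their result (IRF8, XBP1, BCL6, PAX5, CD79B, SYK, LYN, BTK, BLNK, PIK3AP1, SPI1 and MYC). Of the named genes, TAPBP alone had a second probe called in the opposite direction; among all tested genes with names, 2435 had several kept probes and 35 called ones had a probe called the opposite way.

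The procedure was tested on simulated arrays of 19706 features drawn from the real means and spreads of this comparison, with 200 features changed. Of the features changed by 0.25, 0.5, 1 and 2 on the log2 scale, 26%, 66%, 88% and 98% were recovered, and 11 unchanged features were called. Without any change 0 features and 0 lists were called, and a list shifted by 0.3 was found while no other list was called. Simulated features were drawn independently, whereas the real ribosomal protein list had an estimated correlation of 0.39 between members. The simulation therefore does not test how the list tests behave with correlated members. In the data 69.2% of features were called, far more than were changed here, so the recovered shares need not carry over. Alternatives were other scalings, the authors' values, other filters on dim probes, the mean of a gene's probes, another prior, replicate number or slide as a block, each array left out, and other list tests. After the data were examined, normexp with an offset of 50 was run on the median signal, since the planned mean signal is not a column of these files, each chromosome's median was subtracted for genes with names, and members matched only through a synonym were left out of the lists.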

Results

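Gene expression was measured in DT40 cells with and without IRF4, a transcription factor of the interferon regulatory factor family that acts in B cell activation and plasma cell differentiation. The question, as the labels put it, was which transcripts change in unstimulated DT40 B cells when IRF4 is missing. Each of 3 wild-type and 3 IRF4 knockout cultures was hybridised to 1 array, and between 62.4% and 68.2% of gene spots were well above background. Arrays of the same group correlated at r between 0.9969 and 0.9976 over the 19802 tested features, and arrays of different groups between 0.9372 and 0.9383. All fold changes are knockout over wild type with n = 3 in each group, except for LYZ with 2 knockout arrays, and all errors on them are standard errors from limma.

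IRF4 itself was the check on the labels. The brighter of its probes (A_87_P037691) fell from 3.01 ± 0.13 (SD, n = 3) in wild type to -1.21 ± 0.14 (SD, n = 3) in the knockout, in log2 units relative to each array's 75th percentile. That is an 18.6-fold lower signal (log2 fold change -4.21 ± 0.10, limma adjusted p = 5.0e-07), and this probe was still well above background on all 3 knockout arrays. The dimmer probe (A_87_P234013) stood at -3.12 ± 0.06 (SD, n = 3) in wild type and was not well above background on any knockout array, at least 11.2-fold lower. Which part of the gene was disrupted is not given in the sources used here, so neither probe can be placed inside or outside it. An exact permutation test on the brighter probe gave p = 0.1, the smallest p that 3 against 3 arrays allow. Within each of the slides that held an array of both groups, the log2 fold change was -4.28 and -4.33, and with slide as a fixed block it was -4.30.

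**Figure D1:**
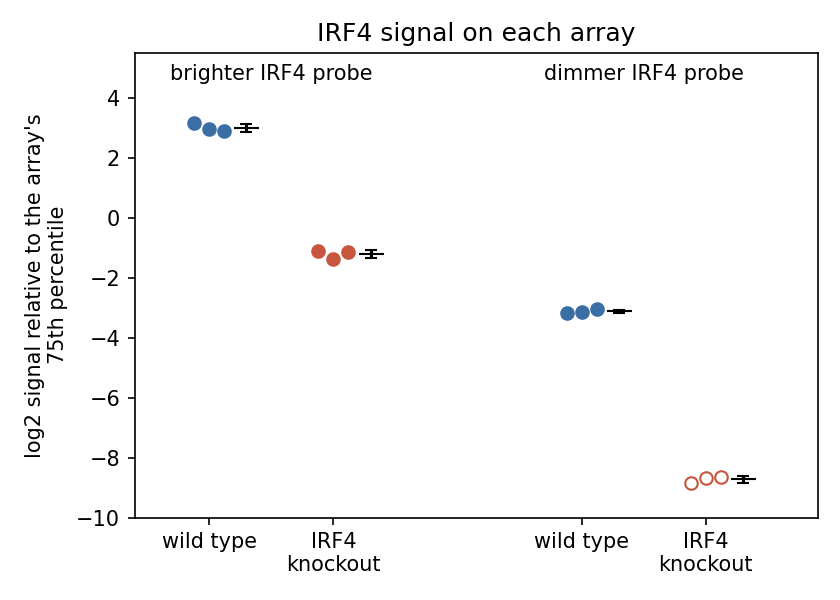
IRF4 signal of both IRF4 probes on each array, on the y axis as log2 relative to the array's 75th percentile; dots are arrays (open where the probe was not well above background on any array of the group) and black bars are means with SD. The brighter probe fell by 4.21 on the log2 scale, and the dimmer probe left the range above background on all 3 knockout arrays.

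Some genes switched between background and clear expression. FLT1, a receptor for vascular endothelial growth factor, was not well above background in wild type and was at least 32.3-fold higher in the knockout. The chemokine receptor CCR9 (at least 11.1-fold), the microtubule-binding protein gene DCX (at least 14.1-fold) and the Src-family kinase gene FYN (at least 6.99-fold) went the same way. USP2, a deubiquitinase gene detected in both groups, rose 40.4-fold, the protocadherin gene PCDHGC3 29.3-fold, GPM6B 22.7-fold and the transcription factor gene CREB3L2 22.1-fold. In the other direction KCNK7, a potassium channel gene, was at least 242-fold lower in the knockout, and the glutathione transferase gene MGST1 at least 117-fold lower. FAM26E (at least 45.8-fold), NUDT14 (at least 41.5-fold), the dynamin gene DNM1 (at least 40.7-fold), SCOC (at least 34.1-fold), ANO5 (at least 30.4-fold) and the cytosolic phospholipase gene PLA2G4A (at least 26.2-fold) were bright in wild type and not well above background on any knockout array. DFNA5 stood at 1.00 ± 0.03 (SD, n = 3) in wild type and was well above background on 1 of 3 knockout arrays, so no fold is given for it. These genes belong to the 12 rises and 12 falls with the largest fitted log2 fold changes. The others of these rises were PI15 (at least 7.36-fold), PKIA (at least 9.14-fold), CRYBB1 (at least 12.8-fold) and WSCD1 (at least 7.94-fold). The others of these falls were MANSC1 (at least 28.5-fold), PKD2 (at least 24.9-fold) and BEAN1 (at least 24.1-fold). Adjusted p for these 24 genes lay between 4.9e-08 and 0.00025 in limma. At background the fitted value is no measured size, so the 24 genes are not ranked here: COL1A2 (18.9-fold higher) and TNFSF13B (44.9-fold lower), measured in both groups, changed by more than several of the bounds.

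**Figure D2:**
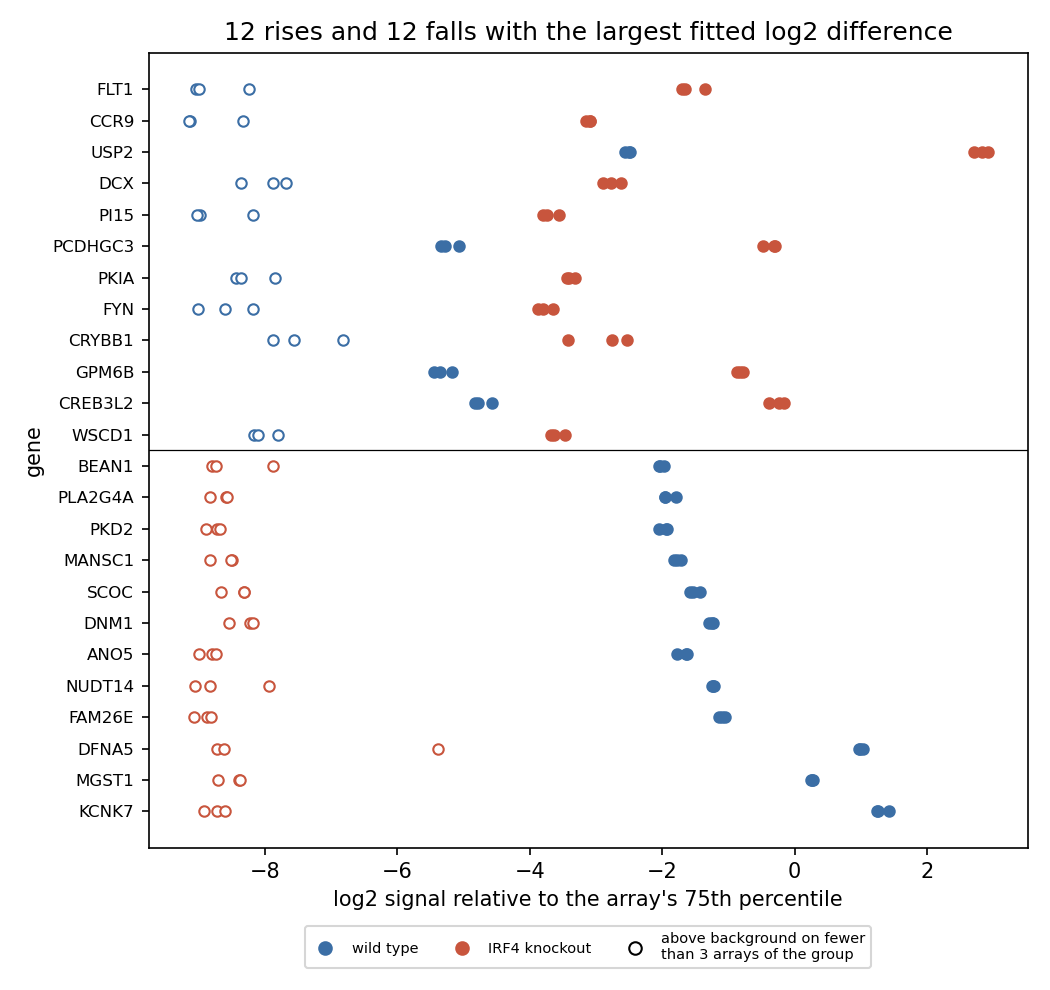
Signal of the 12 rises (top) and 12 falls (bottom) with the largest fitted log2 fold changes on each array, on the x axis as log2 relative to the array's 75th percentile; dots are arrays, open where the gene was well above background on fewer than 3 arrays of that group. By the rule that chose the 24 genes, the 3 knockout arrays of each lie apart from the 3 wild-type arrays. The open dots mark groups whose level was not measured on every array.

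Across all 19802 features 7999 were higher and 5705 lower in the knockout (69.2% called). Of the 3836 tested genes with names, 1464 were higher and 1211 lower, and 242 rose and 271 fell by at least 2-fold (136 and 234 with normexp, 213 and 309 with median centring). In 2921 of them (76.1%) the groups did not overlap, against 10% by chance with 3 arrays against 3. Detection on all arrays of wild type and on none of the knockout was seen for 59 of these genes, and the opposite for 53. Centring each array on its median, which lowered the median log2 fold change of all features by 0.089, gave 6412 higher and 6860 lower features and 1129 higher and 1480 lower genes with names, so the balance of small changes rests on the scaling. With slide as a fixed block 5868 features were higher and 4573 lower. Over 3826 genes with names, called or not, the differences of the slides that held both groups correlated at r = 0.966 across genes.

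Several of these genes lie on chromosomes whose genes shifted together. On the GRCg7b assembly, the chromosome that carries PIK3CA, TFRC, BCL6, BOK, TRPC1 and TNFSF10 had a median log2 fold change of -0.65 over 102 genes. The chromosome of IRF4, MYC, LYN, VIM, BCL2, CDC25A, RIPK1, SGK3, MYO1G, LY6E, COL1A2, DFNA5, CCR9, PI15 and PKIA had a median of -0.43 over 337 genes. The chromosome of KCNK7, FAM26E, FYN, MYB, TRAF5, SDC1, CTSB, ELOVL5 and PPP3R1 had a median of -0.39 over 307 genes, and that of ID3 and RPS6KA1 a median of 0.51 over 65 genes. The median over all 3803 genes placed in this way was 0.051. These 4 lay at least 0.25 from it, a limit chosen after the data were seen. The chromosome of PAX5, SYK, CD72 and FANCG (median 0.17, permutation adjusted p = 0.020) and that of ARHGEF3 and FOXP1 (median 0.23, adjusted p = 0.0066) also passed the permutation test and lay closer.

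B cell receptor signalling genes moved both ways. Of 30 tested members 12 rose and 10 fell, with 8 not called. CD72, a B cell co-receptor with an inhibitory cytoplasmic motif, rose 9.24-fold (log2 fold change 3.21 ± 0.06) and BCL10, an adaptor between antigen receptors and NF-kB, rose 2.14-fold. The tyrosine kinase gene TEC fell by 3.58 on the log2 scale (SE 0.07) and the tetraspanin gene CD81 fell 2.74-fold. SYK (0.57 ± 0.04) and PIK3AP1 (0.34 ± 0.05) rose, and LYN, whose chromosome's genes shifted down (median -0.43), fell (-0.95 ± 0.06). SH2D6 rose too (0.60 ± 0.04), and its place in the list rests only on BLNK being a synonym of it in the reference. BTK (-0.09 ± 0.07, adjusted p = 0.28) and CD79B (0.15 ± 0.07, adjusted p = 0.10) did not pass the test. CD79B passed with the mean of its probes (adjusted p = 0.022) and without knockout replicate 3 (adjusted p = 0.027), and BTK with chromosome medians subtracted (-0.19, adjusted p = 0.043). That subtraction by construction lowered BTK by the median of its chromosome (0.098), which is not among the shifted ones. As a group the list did not stand apart from other features (camera adjusted p = 0.86), and its mean (0.29, or 0.16 with 3 members below background in wild type set at their bounds) and median (0.05) lay above 0 while camera's direction was down.

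The list of the PI3K pathway and inositol phosphatases had 15 tested members, of which 1 rose and 7 fell. PIK3CD and PIK3CA, which encode catalytic subunits of PI3-kinase, fell 2.45-fold (-1.29 ± 0.05) and 2.39-fold (-1.26 ± 0.04), SGK3 fell 1.82-fold and AKT1 1.40-fold (-0.48 ± 0.05). Of the 15 members 5 lie on the shifted chromosomes, among them PIK3CA (chromosome median -0.65), SGK3 (-0.43) and, on the raised one, RPS6KA1 (0.51). RPS6KA1 fell by 0.13 with an SE of 0.04 (adjusted p = 0.026), and it missed the threshold when any of 5 of the arrays was left out, with adjusted p up to 0.083, without the filter (0.080) and with slide as a fixed block (0.19). The list's camera adjusted p was 0.26. Among 17 calcium signalling genes 7 rose and 5 fell (camera adjusted p = 0.82). The ATP-gated channel genes P2RX7 (-2.93 ± 0.06) and P2RX4 (-1.04 ± 0.08) fell, as did PPP3R1, a calcineurin subunit gene (-0.37 ± 0.03), while TRPC1 (0.65 ± 0.05) and CAMK2D (0.59 ± 0.06) rose. The fall of PPP3R1 was lost with the mean of its probes (-0.20, adjusted p = 0.37) and with its chromosome's median subtracted (0.015, adjusted p = 0.70). That list's mean was -0.10, its median 0.09 and its camera direction down.

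Of 19 tested transcription factors of B cells, 9 rose and 5 fell, and the list did not stand apart from other features (camera adjusted p = 0.81). IRF8, the closest relative of IRF4, rose 2.30-fold (1.20 ± 0.05), RUNX1 2.07-fold, SPI1, which encodes the IRF4 partner PU.1, 1.58-fold (0.66 ± 0.06), POU2F1 1.49-fold and PAX5 1.18-fold (0.24 ± 0.06). PAX5 missed the threshold with slide as a fixed block (adjusted p = 0.051) and with its chromosome's median subtracted (0.077, adjusted p = 0.25). ID3, an inhibitor of E proteins, fell 5.00-fold (-2.32 ± 0.07), MYB 2.07-fold and BCL6 1.26-fold (-0.34 ± 0.05). ID3 fell although its chromosome's genes shifted up, whereas MYB and BCL6 lie among genes that shifted down. With its chromosome's median subtracted BCL6 turned to a called rise (0.31, adjusted p = 0.0015). Of 19 tested genes of the plasma cell programme, 6 rose and 11 fell (camera adjusted p = 0.39). CD38, an ectoenzyme of plasma cells, was at least 8.28-fold lower, SDC1, which encodes the plasma cell marker syndecan, fell 1.61-fold, and DNAJB9, a chaperone gene of the endoplasmic reticulum, 1.59-fold. SDC1 lies among genes that shifted down (chromosome median -0.39). CREB3L2 and the receptor gene TNFRSF13B (2.75-fold, 1.46 ± 0.05) rose. XBP1 differed by 0.09 ± 0.06 (adjusted p = 0.22).

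The list of NF-kB and TNF receptor family genes had 16 of 25 members down and 6 up. It passed camera with the preset correlation (adjusted p = 0.046) and not with an estimated one (adjusted p = 0.89). TNFSF13B, which encodes the B cell survival factor BAFF, fell 44.9-fold (-5.49 ± 0.05), TNFSF10, which encodes TRAIL, 6.94-fold (-2.80 ± 0.11), TRAF5 2.13-fold and NFKBIA, an inhibitor of NF-kB, 1.67-fold. TNIP2 rose 2.49-fold. The call was also lost under quantile scaling (adjusted p = 0.12) and with slide as a fixed block (adjusted p = 0.062) but not as a random one (adjusted p = 0.046). The mean of the NF-kB list lay below that of all features by nearly as much in these settings (-0.51 under quantile scaling and -0.50 with the fixed block, against -0.53), and the median member was at -0.35 within each slide that held both groups. The mean draws heavily on TNFSF13B (-5.49): over the 25 members the mean log2 fold change was -0.46 and the median -0.31. Apoptosis genes divided into 5 up and 11 down of 22 (camera adjusted p = 0.42). BAK1 (5.20-fold, -2.38 ± 0.04) and BOK (2.72-fold), whose products promote cell death, fell, as did the kinase gene RIPK1 (1.76-fold). BCL2, whose product inhibits cell death, rose by 1.07 (SE 0.05) on the log2 scale, and the nuclease gene DFFB rose 1.68-fold.

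Of 46 tested cell cycle genes, 22 fell and 6 rose (median log2 fold change -0.21). The list passed camera with the preset correlation (adjusted p = 0.016) and not with an estimated one (adjusted p = 0.32). The estimated correlation of this list, 0.00051, was below the preset one. A higher correlation between its members therefore does not account for the loss, whose cause was not tested. CDC25A (1.88-fold), ORC1 (1.87-fold) and MYBL2 (1.68-fold), which act at entry into S phase, fell, and MYC fell 1.23-fold (-0.30 ± 0.05). With its chromosome's median subtracted MYC turned up and missed the threshold (0.12, adjusted p = 0.058). The cyclin genes CCND2 (2.38-fold) and CCND1 (1.68-fold) rose. The call was also lost with slide as a fixed block (adjusted p = 0.053), though not as a random one (adjusted p = 0.016), and once each chromosome's median was subtracted (adjusted p = 0.054), and the median member was at -0.19 within each slide that held both groups. The mean of the cell cycle list minus that of all features was -0.31, and -0.28 with the fixed block. With chromosome medians subtracted it was -0.19 against placed genes alone. Of 29 ribosomal protein genes 19 rose, 0 fell and 10 were not called (median 0.22; camera adjusted p = 0.046, or 0.89 with an estimated correlation). The mean of the list lay 0.15 above that of all features, but only 0.03 above it under quantile scaling and with the authors' values, and 0.05 with normexp. With chromosome medians subtracted it lay 0.22 above the mean of the 3803 placed genes, the only ones in that setting, so this distance is not comparable with 0.15. RPL22 and RPL37A rose by 0.37 (SE 0.05 and 0.04), RPL19 and RPL13 by 0.33 and RPS4Y1 by 0.28. RPL13 missed the threshold with normexp (adjusted p = 0.067), and RPS4Y1 with normexp (adjusted p = 0.16) and with slide as a fixed block (adjusted p = 0.053). The list's call was also lost under quantile scaling (adjusted p = 0.85) and with slide as a fixed block (adjusted p = 0.062) but not as a random one (adjusted p = 0.046), and the median was 0.13 and 0.26 within the slides.

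Genes of the actin cytoskeleton and of adhesion split almost evenly, with 22 of 57 up and 19 down (camera adjusted p = 0.82). The actin-binding TMSB4X rose 2.99-fold (1.58 ± 0.04), ARHGEF3 3.71-fold and the actin bundler gene PLS3 1.92-fold. The hyaluronan receptor gene CD44 fell 3.69-fold (-1.88 ± 0.07) and the myosin gene MYO1G 2.38-fold. The mean of the list was 0.05 and its median 0.01, with camera's direction down. Of 13 receptors and regulators of migration 5 rose and 6 fell (camera adjusted p = 0.75). GPR183, an oxysterol receptor that guides B cells in follicles, was at least 4.74-fold higher and CCR9 at least 11.1-fold higher. RGS2 (2.83-fold), CXCR7 (1.97-fold) and GNG2 (1.77-fold) fell, and the list's mean was 0.42 (0.16 with both of these at their bounds), its median -0.22 and its camera direction down.

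In antigen presentation and costimulation 6 of 15 members rose and 6 fell (camera adjusted p = 0.86). CD88, whose place in the list rests only on CD80 being a synonym of it in the reference, rose 3.86-fold (1.95 ± 0.08). The cathepsin gene CTSB rose 2.60-fold and DMA, a class II peptide-loading gene, 1.96-fold, whereas the cathepsin gene CTSS fell 1.79-fold. TAPBP rose by 0.91 with its brighter probe, but its other probe was called in the opposite direction and the mean of both gave -1.03. The list's mean was 0.10 and its median 0.06, with camera's direction down. Of 18 interferon response genes 10 rose and 5 fell (camera adjusted p = 0.75). IRF7 (3.66-fold, 1.87 ± 0.05), SOCS3 (3.42-fold) and LY6E (1.89-fold) rose, while IRF1 (2.43-fold, -1.28 ± 0.07) and SOCS1 (2.34-fold) fell.

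Of 35 genes of immunoglobulin diversification and DNA repair, 14 rose and 13 fell (camera adjusted p = 0.74). LIG4, the ligase of non-homologous end joining, fell 6.43-fold (-2.68 ± 0.07) and the uracil glycosylase gene UNG 1.79-fold. DNTT, the terminal transferase that adds bases at immunoglobulin joints, rose 3.46-fold (1.79 ± 0.09), FANCG 1.94-fold and POLQ 1.66-fold. In cholesterol and fatty acid synthesis 12 of 18 members rose and 3 fell (median 0.50, camera adjusted p = 0.30). The desaturase gene SCD rose 2.65-fold (1.41 ± 0.13), DHCR7 2.00-fold, FASN 1.76-fold and ACLY 1.43-fold, and the elongase gene ELOVL5 fell 2.06-fold. Among 28 glycolysis and hypoxia genes 10 rose and 5 fell (camera adjusted p = 0.82). The lactate transporter gene SLC16A3 rose 5.26-fold (2.40 ± 0.11), P4HA1 2.54-fold and HK1 1.40-fold, while P4HA2 fell 6.80-fold and PDK1 1.36-fold.

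Markers of other cell types moved both ways too. Of 7 genes matched to T cell markers, 2 rose and 4 fell (camera adjusted p = 0.63), and without FOXP1, which the reference matched to FOXP3 through a synonym, 1 of 6 rose and 4 fell (adjusted p = 0.33). CD3E fell 10.8-fold (-3.44 ± 0.08), CD8A 2.19-fold and GNLY 1.47-fold, while CD5, which B cells can also carry, rose 2.95-fold (1.56 ± 0.06). FOXP1 rose 1.24-fold and missed the threshold with its chromosome's median subtracted (adjusted p = 0.12). Of 12 macrophage and myeloid markers 5 rose and 4 fell (camera adjusted p = 0.75). TIMD4 (4.22-fold), MMP9 (2.19-fold) and FCER1G (1.54-fold) rose, and CEBPB (2.56-fold) fell. The lysozyme gene LYZ fell by 1.69 between 3 wild-type and 2 knockout arrays, its outlier-flagged spot on the other knockout array being left out, and did not pass with the authors' processed values (adjusted p = 0.098). Of 8 fibroblast and stroma markers 5 rose and 1 fell (camera adjusted p = 0.47). COL1A2 rose 18.9-fold (4.24 ± 0.06), COL6A3 1.45-fold and COL5A1 1.29-fold, COL6A1 was at least 1.22-fold higher, and VIM fell 3.32-fold. Of 7 erythroid and thrombocyte markers 1 rose and 3 fell (camera adjusted p = 0.47). TFRC fell 2.02-fold, H1F0 1.82-fold and HBBA 1.91-fold, the last above background on 2 knockout arrays, and HBAD rose 1.26-fold, just missing the threshold with slide as a fixed block (adjusted p = 0.0501).

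**Figure D3:**
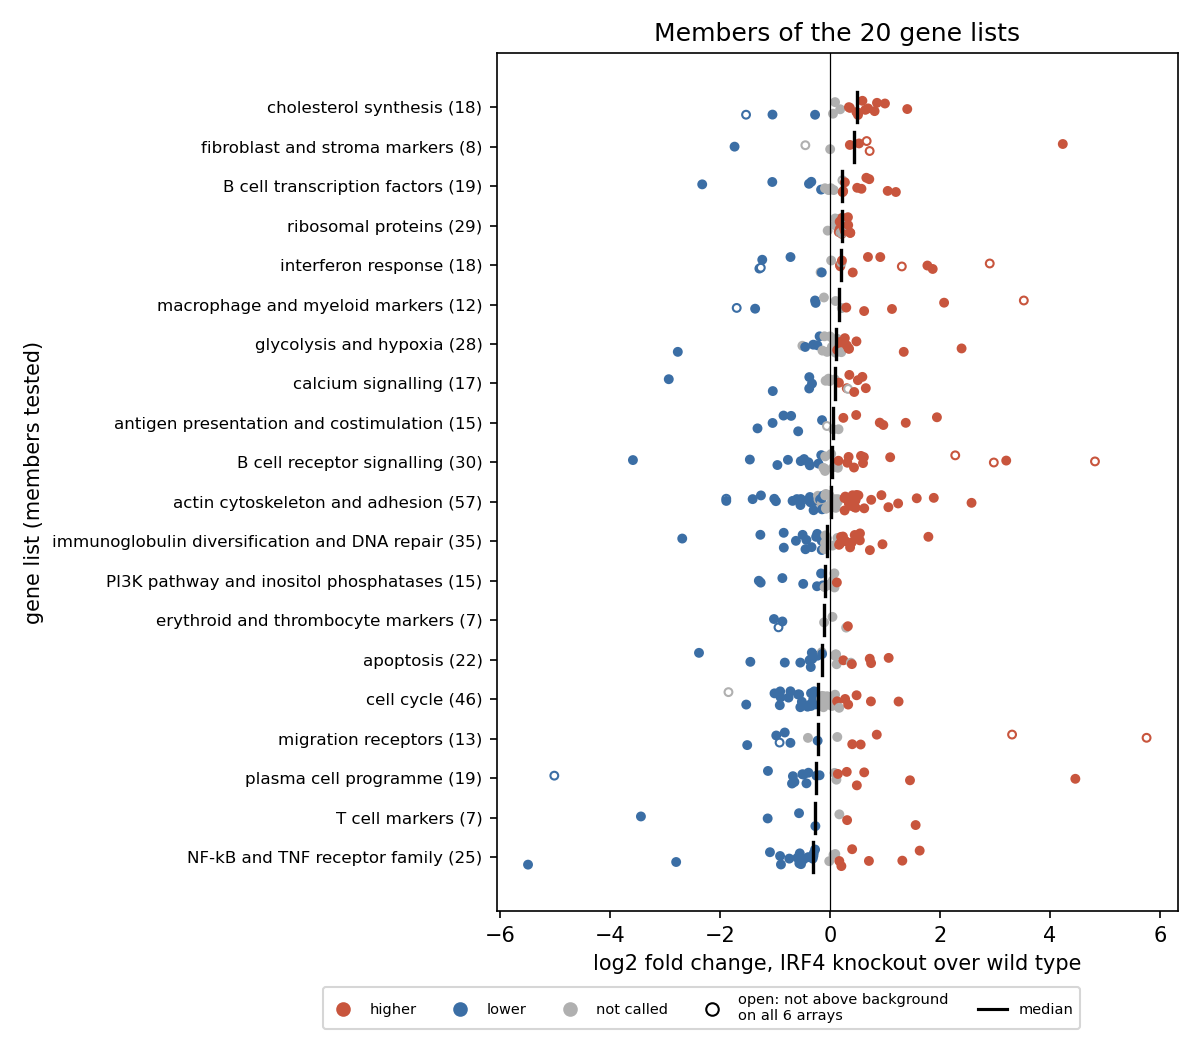
Log2 fold change, knockout over wild type, on the x axis for each tested member of the 20 gene lists; dots are genes, coloured by limma call and open where not well above background on all 6 arrays, and black bars are list medians. Ribosomal protein genes sit close together around 0.22, whereas the members of the B cell receptor list measured in both groups run from -3.58 (TEC) to 3.21 (CD72) around a list median of 0.05.

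Counts adjusted over the list alone were the same as those over all features for 18 of the 20 lists. The exceptions were apoptosis, with 6 up and 11 down, and the PI3K list, with 0 up and 6 down. With an estimated correlation no list passed camera, and the adjusted p was 0.89 for every list except cell cycle at 0.32. Fry was run in the main scaling alone, where the median log2 fold change of all features was 0.089. The B cell receptor, actin and antigen presentation lists, which it passed upwards, had medians below that (0.048, 0.015 and 0.063). Minus the mean of all features, their means were 0.22, -0.02 and 0.03. Fry sets no list against other genes, and whether these passes rest on the scaling was not tested.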

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

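Alternatives chosen after the data were seen were normexp on the median signal, the subtraction of each chromosome's median and lists without synonym matches. IRF4 kept its fall under all alternatives, between -4.91 (mean of its probes) and -3.79 (chromosome medians subtracted). Over all alternatives 2306 values of single named genes and 366 of list tests kept their direction and their side of the threshold. Of the values of counts and of IRF4, 127 were marked as the same and 5 as moved, which for counts does not cover the balance of rises and falls. Of the list tests 26 lost the threshold without turning, 13 gained it and 15 turned direction. Of the values of single named genes 16 lost the threshold without turning, 3 gained it and 8 turned direction. Among the named genes that turned, MYC and PPP3R1 also lost the threshold. The signal over background limits the 59 and 53 genes detected in 1 group alone, whose folds are bounds.

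The replicate numbers did not pair the samples: deviations of same-numbered arrays from their group means correlated at -0.026, -0.012 and -0.015, and no array correlated best with its own number. With the replicate block 7571 features were higher and 5454 lower, which is within 1.5 times of the counts without it. Slide as a random block, with a correlation of 0.027 between arrays of a slide, gave 8014 and 5721.

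A threshold of 2-fold left 1612 features higher and 1348 lower, and 242 and 271 genes with names, by its construction. With normexp 136 genes with names rose and 234 fell by at least 2-fold, and with median centring 213 and 309. For features these counts were 950 and 1053 with normexp, and 1441 and 1514 with median centring. Median centring lowered the log2 fold change of every feature measured on all 6 arrays by the same 0.089, so its counts moved by construction. The offset of 50 in normexp shrinks the fold changes of dim features by construction, but its share in the normexp counts was not tested. For the changes below the cause was not tested unless its construction is named.

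The NF-kB and TNF receptor list kept its direction but missed the threshold with the authors' values (adjusted p = 0.12), an estimated correlation (0.89), median centring (0.073), chromosome medians subtracted (0.14), normexp (0.082), quantile scaling (0.12) and slide as a fixed block (0.062). Ribosomal proteins missed it under the same settings, with adjusted p of 0.86, 0.89, 0.073, 0.054, 0.77, 0.85 and 0.062. With chromosome medians subtracted their mean lay 0.22 above that of the 3803 placed genes, against 0.15 above that of all features in the main fit. The reference differs, so these distances are not comparable, and every list test in that setting has this smaller reference. Cell cycle missed it with an estimated correlation (0.32), chromosome medians subtracted (0.054) and slide as a fixed block (0.053). The block on slide draws on fewer arrays, since only the slides with both groups inform it. Leaving out 1 array gave adjusted p from 0.035 to 0.080 for NF-kB, missing the threshold without knockout replicate 3, wild type replicate 2 or wild type replicate 3. It gave 0.012 to 0.089 for ribosomal proteins, missing it without any of these or without knockout replicate 1. Without synonym matches the NF-kB list, which has none, and the ribosomal list, which lost 3 members, both came to 0.0591, the former through the adjustment over all lists.

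Lists that were not called turned camera's direction in some settings. B cell receptor signalling turned up with the authors' values (adjusted p = 0.98), no filter on dim probes (0.97), normexp (0.92) and quantile scaling (0.99). Glycolysis turned down with the authors' values (0.89), chromosome medians subtracted (0.97), normexp (0.77) and quantile scaling (0.88), and without knockout replicate 3, with 0.77 to 0.95 over the left-out arrays. Actin and calcium signalling turned up with chromosome medians subtracted (0.97 each), and calcium also with the mean of a gene's probes (0.82).

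Fry ignores other genes, kept the main scaling and passed lists camera did not. Upwards these were B cell receptor signalling (adjusted p = 0.012), actin (0.033) and antigen presentation (0.023), all turned from camera's direction, and B cell transcription factors (0.0031), cholesterol synthesis (0.023), fibroblast (0.00077), glycolysis (0.039), interferon (0.00044) and myeloid genes (0.00070). Downwards these were PI3K (0.00070), T cell (0.0015), apoptosis (0.00017), calcium (0.0078), erythroid (0.0031), migration (0.0094) and plasma cell genes (0.0074).

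Of the named genes, BCL6 (0.31), MYC (0.12) and PPP3R1 (0.015) turned up once the median of their lowered chromosomes was subtracted, which follows from that subtraction. TAPBP turned to -1.03 with the mean of its probes, which are called in opposite directions. XBP1, not called, came to -0.0042 with the authors' values, -0.0026 with median centring, -0.00038 with chromosome medians subtracted and -0.0046 with quantile scaling.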

Other observations

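The tests on single arrays, segments of chromosomes, slides, falls on the lowered chromosomes and CD3D were chosen after their results were seen, and so was the division of genes by chromosome; the tests on other scalings, brighter genes and other splits were set before their results were seen.

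Genes of 4 chromosomes shifted together. Of 30 chromosomes with at least 20 tested genes, 26 had median log2 fold changes between 0.046 and 0.23. The 3 lowered ones, which carry PIK3CA (median -0.65), IRF4 (median -0.43) and KCNK7 (median -0.39), and the raised one, which carries ID3 (median 0.51), lay outside that range, each with a permutation p of 1e-04, the smallest that 10000 permutations can give (adjusted p = 0.00075). On the lowered chromosomes lay 43.5% of the placed genes with names called lower, against 19.6% of the placed genes tested.

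Under quantile scaling, normexp and the authors' values the 4 medians stayed at least 0.419 away from the median of all placed genes, which argues against brightness-dependent scaling. On single knockout arrays the distance was at least 0.423, and among the brighter genes of each chromosome at least 0.429, which argues against 1 unusual array and against an effect of dim genes. A candidate explanation is a different number of copies of these chromosomes in the knockout line: in each of 4 segments of each chromosome, cut to equal numbers of genes, the median lay at least 0.281 to the same side. In proportion to copies, a change from 3 to 2 would give -0.58 on the log2 scale, one from 2 to 1 would give -1 and one from 2 to 3 would give 0.58. From the median of all placed genes, the chromosomes of PIK3CA, IRF4, KCNK7 and ID3 lay at -0.70, -0.48, -0.44 and 0.46. None of these equals a value in proportion to copies. No DNA was measured here, and a shift that came with IRF4 loss and one that arose in a subclone stay open.

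Most genes differed between the lines. With limma the real division of the 6 arrays called 13704 features and the highest of the other divisions called 0. Each other division mixed arrays of both lines, so the difference between the lines added to the spread within its groups. A low count there was therefore built in. Only the real division, 1 of 10, gave as many, and with 10 divisions no share under 0.05 can be had. Over all tested genes with names, called or not, the differences of the slides that held both groups, made from different arrays, correlated at r = 0.966 across genes (not independent replicates), which argues against differences between slides. Chromosome-wide shifts alone do not account for the falls: 681 of 1206 placed genes called lower lie off the lowered chromosomes. On the lowered ones 51.6% (271 of 525) stayed called lower with the median subtracted, and 64 turned to called rises. Those 271 fell further than their chromosome's median. Subtracting a median leaves as many genes below it as above by construction. The share, just above the 50% set as the limit, therefore decides nothing. A test set earlier, over all 1206, gave 78.9% but was largely fixed by the 681, and the other falls on the lowered chromosomes may come from the shifts. How many knockout clones the cultures came from is not given in the sources used here, so effects of IRF4 loss and divergence between the lines stay open and were not tested.

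CD3E and CD8A were lower in the knockout. T cells among the wild-type cells were weighed as a source, although the sample titles name only B cells of the line DT40. CD3D, chosen after its value was seen, differed by 0.17 ± 0.07 on the log2 scale (adjusted p = 0.077) where CD3E fell by 3.44. CD3D was far above the array's 75th percentile in both groups (6.01 and 6.18), so B cells may hide a loss of T cells, and the test, at first read as arguing against T cells and reread after its value was seen, decides nothing. CD247, also chosen after its value was seen, fell by 0.26 on the log2 scale (SE 0.06), but how much of it B cells make was not measured, so the source stays open.

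Neighbouring genes also resembled each other. For this, log2 fold changes beyond 1 in size were set to 1 with their sign kept. The values of 3773 adjacent pairs then correlated at r = 0.175 across genes, which are not independent replicates, against at most 0.063 in permuted orders. With chromosome medians subtracted r was 0.050 (permutation p = 0.0014), below the highest permuted value of 0.061.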
